A study of Mus musculus with 12 samples.

How the data were processed

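Expression was measured in CD8+CD28low regulatory T cells from wild-type C57Bl/6 mice and from mice of the same strain that lack Aire, per the labels. The cells were either freshly isolated (native) or cultured for 96 h with allogenic antigen-presenting cells and an anti-CD3 antibody (activated). Each of the 4 groups held 3 arrays whose titles call them biological replicates. The labels do not say how many mice stand behind an array or how the cells were isolated, and the p-values of single genes measure the spread between these arrays.

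Total RNA was extracted with Trizol, purified on RNeasy columns and turned into biotin-labelled sense DNA with the Affymetrix whole-transcript sense target labelling assay, per the labels' protocols. The deposited table held 35556 log2 expression values for each of 12 arrays, 1 per transcript cluster, and the authors made it with Partek and RMA, per the submitters' processing notes. Program versions and the options of RMA are not given in the sources used here. RMA in its usual form corrects background, aligns the arrays' distributions at the level of probes and summarises the probes of a transcript cluster on the log2 scale. It compresses differences close to background, and an alignment hides a change that moves most transcripts in the same direction. Whether the arrays were aligned is not settled by the sources used here: the interquartile range of the deposited values differed between arrays, from 2.19 to 2.89.

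Transcript clusters were named through the platform's annotation, with symbols updated through Entrez identifiers to the mouse gene table of GRCm38.p6. One symbol was given for 21789 transcript clusters, several for 1621 and none for 12146; 21698 of the first kind were matched to the gene table. Where a gene had several transcript clusters (999 genes) the brightest over all 12 arrays was kept, which left 19938 genes. On activation, 5 of those 999 genes had transcript clusters called in opposite directions. The 13767 transcript clusters without a single symbol were left out of the comparisons of named genes and were tested only in a fit of the whole table. No filter on dim genes was used. A gene was taken as at background in a group where all 3 arrays lay at or under the 95th percentile of the olfactory receptor genes on the same array. The bound of its difference was then computed from that percentile, or from the gene's own value where that was higher, in place of its level. Read depth has no counterpart on arrays, and the number of arrays per group limits the precision.

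Group means were fitted over all 12 arrays in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). All groups then shared 1 estimate of the spread per gene. The Benjamini-Hochberg adjustment ran over the 19938 genes, and a gene was called at an adjusted p under 0.05. The comparisons were Aire-deficient against wild-type cells in the native state, in the activated state and as the mean of both states, the interaction of genotype and state, and activated against native cells in each genotype. Errors given with log2 differences are standard errors of that fit, with 3 arrays per group. The groups differed in spread: the median standard deviation of a gene was 0.0989 in native WT, 0.122 in native KO, 0.159 in activated WT and 0.247 in activated KO. For many genes the shared error is thus wider than the native arrays alone would give and narrower than the activated KO arrays would give. The p-values of that fit carry the same limit.

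Before the data were examined, 35 gene lists were fixed, covering T cell programmes, metabolic and stress programmes, markers of other cell types and technical classes such as sex-linked genes. The list of ribosomal protein genes was drawn by the prefixes Rpl and Rps, and that of small RNA genes likewise by prefix, so that they also took in a few other genes. In the glycolysis list Gpi1 was matched through an older symbol to Pigq. The tests were repeated without these members as an alternative added after the data had been seen. Apart from those drawn by prefix, the lists hold 534 genes, of which 489 were measured, and 33 lists had at least 5 measured members and were tested. The test was camera from limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated for each list, and fry, were run beside it. Camera sets a list against the other genes, and at the preset correlation its p-values treat genes as nearly independent. They do not measure the spread between arrays alone. The genes named were also chosen by a rule fixed then. For each comparison it took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap. For the mean and the interaction the groups could overlap. Where fewer passed, the rule took the smallest unadjusted p-values up to 5 per direction, given as values that did not pass. It also took up to 4 members of each list with the largest absolute difference, and always Aire. Predicted gene models and transcript clusters with several symbols were left out.

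Correlations of log2 differences were computed across genes, which are not independent replicates. The correlation of the 2 genotype comparisons was set against 100 relabellings of the arrays within each state. The fit was tested on simulated data made from the arrays' levels and spreads, with 100 genes changed at each fold. In the native genotype comparison it recovered 69% of 2-fold and 97% of 4-fold changes with 5 false calls. In the activated comparison it recovered 77% and 97% with 107 false calls, more than the changed genes recovered at either fold. In the mean of both states it recovered 89% and 100% with 17, and in wild-type activation 68% and 96% with 23. In the real native comparison fewer genes had a small unadjusted p-value than chance gives (limma, 131 where 997 would be expected). The shares describe the simulated data and cannot be taken as the recovery on the real arrays. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

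Replicate numbers in the titles are shared between groups, and the pairing was checked before any fit with a block was compared. Deviations from the group means correlated between native arrays of the same number at 0.580, 0.396 and 0.157 (Pearson's r across genes). The highest r of native WT arrays 1, 2 and 3 with a native KO array of another number was -0.206, 0.0525 and 0.130. The numbers were thus taken to pair the native arrays of the 2 genotypes, but for number 3 the margin was small and the pairing is not settled. Between activated arrays of the same number the values were 0.694, -0.0166 and -0.0130, and these numbers were not taken as pairs. Alternatives covered the filter on dim genes, the transcript clusters tested, a second quantile normalization, median centring, the eBayes options, array weights, thresholds, blocks, the arrays in the fit and leaving out each array in turn. Others were added after the data had been seen.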

Results

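RNA from CD8+CD28low T cells, a regulatory subset of CD8 T cells that carries little of the costimulatory receptor CD28, was measured on 12 whole-transcript arrays. The arrays fell into 4 groups of 3: native wild type (WT), native Aire-deficient (KO), activated WT and activated KO. Deposited log2 values ran from 3.81 to 15.4. Arrays of a group correlated with each other at a mean Pearson's r across genes of 0.994 in native WT, 0.992 in native KO, 0.983 in activated WT and 0.962 in activated KO. The first principal component held 68.2% of the variance and separated native from activated arrays. The second held 16.6% and set activated KO array 3 apart, at a score of -63.79 where the other 11 arrays lay between -6.35 and 28.71. That array also had the narrowest interquartile range (2.19) and the highest median of olfactory receptor genes (6.34, against 5.49 to 5.95 on the others), which T cells are not known to express and which mark the lower end of the scale. A gene is called at background in a group below where all 3 arrays lay at or under the 95th percentile of these genes on the same array, and a difference with 1 group at such a level is given as a lower bound.

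**Figure D1:**
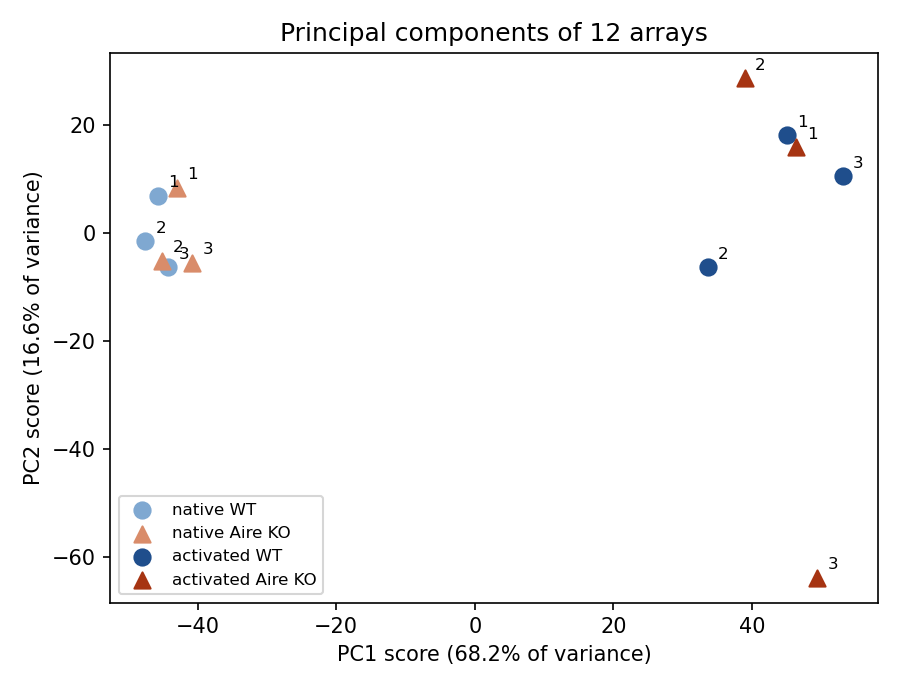
Scores of the 12 arrays on the first and second principal components of the log2 values, with the percent of variance on each axis and 1 point per array, coloured by group and labelled by array number. Native and activated arrays separate on the first component (68.2%), and activated KO array 3 lies at -63.79 on the second (16.6%).

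Aire, the transcriptional regulator that drives display of tissue antigens in thymic epithelium, is the gene missing from the KO mice. It lies on chromosome 10 at 78030022 to 78043610 (GRCm38.p6). Its log2 level on arrays 1, 2 and 3 was 5.83, 5.92 and 5.70 in native WT cells and 5.61, 5.73 and 5.73 in native KO cells. After activation it was 5.56, 5.78 and 5.55 in WT and 5.73, 5.62 and 5.89 in KO cells. All 12 values lay within the range of the olfactory receptor medians. The KO minus WT difference was -0.13 ± 0.11 (SE, n = 3 per group) in native and 0.12 ± 0.11 in activated cells, so the array gave no signal by which the genotype labels could be checked. The place of the probes relative to the deleted part of the gene is not given in the sources used here. Genes within the same stretch of chromosome 10 as Aire can differ between a knockout and its control through flanking DNA. Of 22 measured, 4 lay higher in native KO than in native WT cells, with a list median of -0.06 (camera, adjusted p = 0.0503, and 0.0479 with the replicate number as a block; from 0.0227 without native WT array 1 to 0.767 by fry over all alternatives). In the mean of both states the median was -0.07 and the list was called lower (camera, adjusted p = 0.00525; adjusted p = 0.159 with an estimated correlation), with 0 members passing adjusted over the list alone. That call was lost without native WT array 3 (0.0518), activated KO array 3 (0.0684) or activated WT array 3 (0.143, median -0.0449).

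The first comparison asked how freshly isolated KO cells differed from WT cells, in a study whose title concerns a failure of such cells to control colitis without Aire. Native KO cells held higher levels of granulocyte transcripts as a group. The list calls that follow are those of camera, while fry called 0 lists in native cells. All 12 measured neutrophil markers lay above WT with a median difference of 1.12 (camera, adjusted p = 1.05e-33; adjusted p = 0.0331 with an estimated correlation). In 4 of them the WT level lay at background and left no bound above 0, and the median was the same with these 4 set to 0. Of these, 0 passed over all genes and 1 rose adjusted over the list alone, Retnlg, a resistin-like protein of granulocytes, at 2.10 ± 0.26 (SE, n = 3 per group). Values that did not pass were 2.49 ± 0.90 for Ngp, a granule protein, 1.62 ± 0.61 for S100a8, a subunit of calprotectin, and 1.28 ± 0.57 for Ltf, lactoferrin. On WT arrays 2 and 3 Retnlg (6.10 and 5.48), S100a8 (5.89 and 5.47) and Ltf (5.70 and 5.30) lay under background levels of 6.23 and 6.41. They lay above background on WT array 1, so no bound was computed, and their sizes rest in part on values at background. The list's mean level was 7.87, 5.88 and 7.37 on KO arrays 1, 2 and 3, and 6.45, 5.75 and 5.41 on WT arrays 1, 2 and 3. Macrophage and dendritic cell markers moved with it: 19 of 25 lay higher, with a median of 0.11 (adjusted p = 2.3e-10; adjusted p = 0.0675 with an estimated correlation). Csf1r, the member at that median, lay at background in both native groups, so the median gives no size. Cd14, Adgre1, Fcgr1, Clec4n, Clec9a, Flt3, Ms4a7, Tlr4, C1qa, C1qb and C1qc lay at background there too. Lyz2, lysozyme, differed by 2.19 ± 0.65. Of 8 MHC class II genes, 7 lay higher with a median of 0.39, or 0.23 with members at background at their bound (adjusted p = 5.98e-06; adjusted p = 0.0577 with an estimated correlation), among them Cd74, the invariant chain, at 1.21 ± 0.45 and H2-Aa, higher by at least 0.27 from a WT level at background. KO array 1 carried part of these values: without it the neutrophil list's median was 0.58, Ltf differed by 0.55, S100a8 by 0.99 and Cd74 by 0.73 (0.80 without WT array 3), and H2-Aa had no bound above 0.

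Receptors first described on natural killer (NK) cells were also higher in native KO cells. All 16 measured NK-type receptors and adaptors lay above WT, with a median of 0.47 (camera, adjusted p = 1.14e-22; adjusted p = 0.0214 with an estimated correlation), and 0 passed adjusted over the list alone. Klrc1, the inhibitory receptor chain NKG2A, differed by 0.74 ± 0.23 (SE, n = 3 per group), the adaptor chain Tyrobp by 1.02 ± 0.37 and Ncr1, the NK receptor NKp46, by 0.64 ± 0.40. Ncr1, Klrb1c, Klra8, Fcer1g and Tyrobp also belong to the shorter list of NK cell markers, so these lists are not independent. The shorter list of NK cell markers had a median of 0.31 with 9 of 9 higher (adjusted p = 8.07e-10; adjusted p = 0.0577 with an estimated correlation). Transcription factors and receptors of effector and memory T cells were higher in 14 of 16 cases, median 0.27 (adjusted p = 9.65e-09; adjusted p = 0.0577 with an estimated correlation), with Cd44, an adhesion receptor of memory cells, at 0.44 ± 0.27. Cytotoxic effectors lay higher in 15 of 19 cases, median 0.12 (adjusted p = 1.81e-05; adjusted p = 0.148 with an estimated correlation). Fasl and Gzmb, which encode a death ligand and granzyme B, both differed by 0.51, with errors of 0.24 and 0.25. Cell cycle genes lay higher in 29 of 31 cases, median 0.13 (adjusted p = 1.66e-11; adjusted p = 0.199 with an estimated correlation), with the mitotic kinase Cdk1 at 0.38. None of these lists had a member past the threshold adjusted over the list alone. No single array left out ended the calls of the 8 lists described so far, but sizes depended on single arrays. The NK-type median was 0.31 without KO array 1, the effector and memory median 0.17 without WT array 3, the cell cycle median 0.0631 without KO array 3, and the cytotoxic median 0.0587 without KO array 1 and 0.0655 without WT array 2. Ncr1 differed by 0.33 without KO array 1 and 0.39 without WT array 2, Cd44 by 0.23 without WT array 1, Gzmb by 0.31 without WT array 3 and Cdk1 by 0.24 without KO array 3. Between native arrays of the same number, the KO list mean lay above WT for all 8 lists at numbers 1 and 3. At number 2 it lay below WT for 5 of them: effector and memory genes (-0.11), MHC class II genes (-0.14), and the cell cycle, macrophage and dendritic, and cytotoxic lists. The neutrophil list mean of each array was added as a covariate after the data were seen. With it the calls of the macrophage and dendritic (camera, adjusted p = 0.0529), MHC class II (0.161), NK cell (0.271) and cell cycle (0.0805) lists were lost. Over all alternatives the adjusted p of these 4 lists ran from 6.71e-16 to 0.767. The covariate itself differed between native KO and WT cells, so a lost call cannot tell a common source from separate differences between the genotypes.

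**Figure D2:**
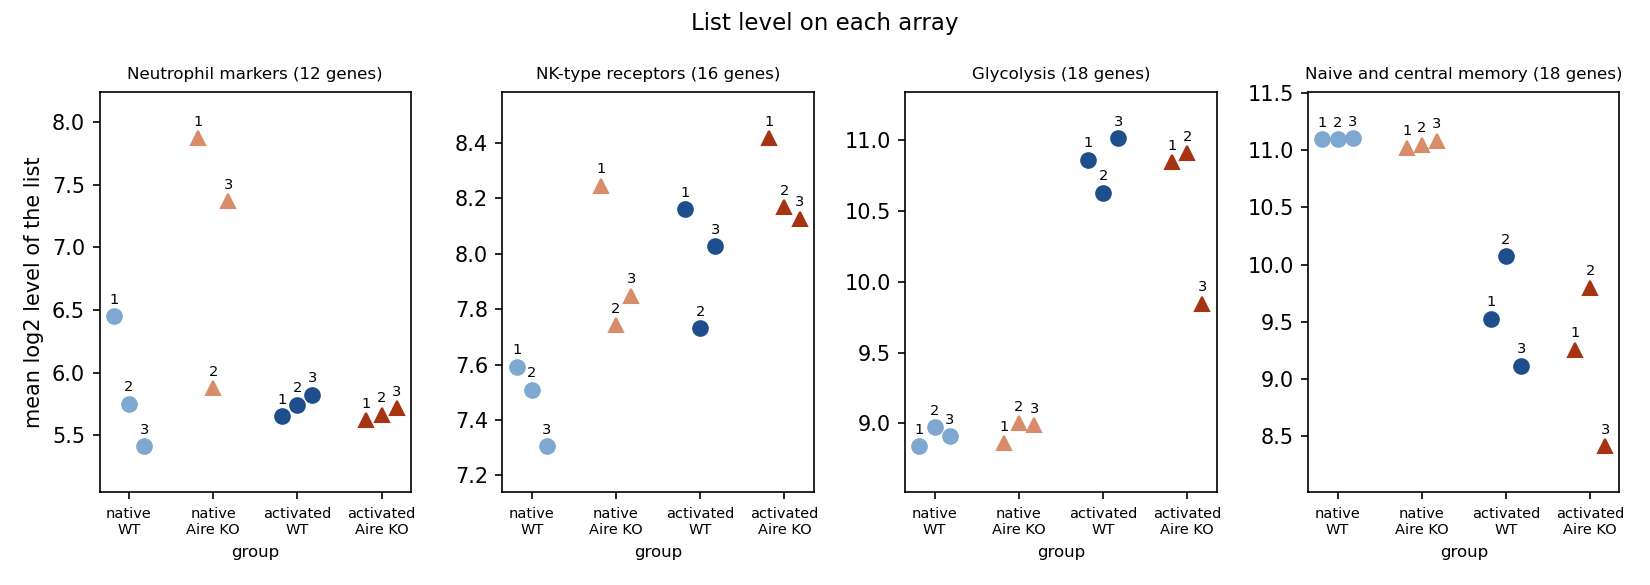
Mean log2 level (y axis) of the neutrophil, NK-type receptor, glycolysis and naive and central memory lists on each array by group (x axis), with 1 point per array labelled by its number. The neutrophil list reached 7.87 and 7.37 on native KO arrays 1 and 3 and lay between 5.62 and 5.82 on the activated arrays.

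Another 10 lists were called in native cells and lost the call without at least 1 array. Regulatory T cell genes (median 0.08, adjusted p = 0.0429; adjusted p = 0.451 with an estimated correlation) lost it without any single array except WT array 1, at adjusted p from 0.0703 to 0.188. Thymocyte markers, the list called lower (median -0.09, adjusted p = 0.0429; 0.19 with an estimated correlation), lost it without KO array 1 (0.0862), KO array 2 (0.243), WT array 1 (0.184) or WT array 3 (0.112). Apoptosis regulators (0.03, 0.011; 0.411 estimated) lost it without KO array 1 (0.137), KO array 2 (0.0943) or WT array 3 (0.0572). Immediate early genes (0.09, 0.00299; 0.478 estimated) turned direction without WT array 1 (0.626) or KO array 2 (0.649). Chemokines and their receptors (0.08, 0.00726; 0.199 estimated) lost it without WT array 1 (0.0969) or KO array 2 (0.0943). Inhibitory receptors (0.16, 0.00184; 0.19 estimated) lost it without KO array 2 (0.0833). Plasma cell markers (median 0.02, mean 0.27, 0.000569; 0.0577 estimated), whose median changes sign with the scaling, lost it without KO array 2 (0.135), and 1 of them rose adjusted over the list alone: Jchain, the joining chain of secreted antibodies, by at least 0.56 from a WT level at background, or 0.28 without KO array 1. B cell markers (0.07, 0.00235; 0.209 estimated) lost it without KO array 1 (0.179). Erythroid and platelet markers (0.14, 0.000569; 0.0819 estimated) lost it without WT array 2 (0.0948). The 71 genes with an Rpl or Rps symbol (0.05, 0.000318; 0.419 estimated), of which 6 are kinases of the S6 kinase family and 4 others a binding partner, a retrogene or pseudogenes, lost it without WT array 1 (0.0519) or WT array 2 (0.138); the other 61, which encode ribosomal proteins or close relatives of them, were at 2.29e-05 (0.37 estimated). On each native array the median level of thymocyte markers, and that of B cell markers, lay under that array's background level. The median differences of both lists may thus rest on values at background and give no size. Without KO array 1 the median differences were -0.00434 for B cell, -0.00653 for apoptosis and -0.0585 for thymocyte genes. Without KO array 2 they were -0.0259 for plasma cell and -0.0685 for immediate early genes. Without KO array 3 they were 0.0115 for chemokines, 0.068 for erythroid and platelet markers, 0.0475 for immediate early, 0.0291 for B cell and 0.0223 for Rpl and Rps genes. Leaving out WT array 1 gave -0.0811 for immediate early and 0.0324 for Rpl and Rps genes, WT array 2 gave 0.0378 for erythroid and platelet, 0.0304 for B cell and 0.00537 for Rpl and Rps genes, and WT array 3 gave 0.0938 for inhibitory receptors and 0.0487 for regulatory T cell genes. Lists that were not called included naive and central memory genes (median -0.06, adjusted p = 0.922), TCR signalling genes (-0.02, 0.906), cytokines (0.03, 0.217, and called higher at 0.0176 without KO array 1), TGF-beta pathway genes (-0.05, 0.161) and gut homing receptors (-0.11, 0.227). In the naive and TCR lists the test pointed upwards while median and mean lay below 0. CD4 T cell markers were not called (0.04, 0.103) but were with the replicate number as a block (adjusted p = 0.0358, higher), with a range over all alternatives from 0.029 without KO array 1 to 0.872 by fry.

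Across single genes, limma called 0 of 19938 between native KO and WT cells in the fit of all 12 arrays, and 0 with the replicate number as a block. Array numbers were taken to pair the native arrays, with a small margin for number 3. In a fit of the 6 native arrays alone with the experiment number as a block, added after the data were seen, 14 genes were called, all higher in KO cells. These were Retnlg at 2.10, Ifitm3 at 1.39, Fcer1g, an Fc receptor chain, at 0.92, Kdm5d at 0.77, Uty at 0.69, Ifng, the cytokine interferon gamma, at 0.68, Ctla2b at 0.67, Cxcr5 and Xcl1 at 0.66, Ncr1 at 0.64 and Ifitm2 at 0.61, and, with WT levels at background, Igha, Jchain and Ceacam1, higher by at least 0.73, 0.56 and 0.21, with adjusted p from 0.0112 to 0.0434, each chosen after its values were seen. Without KO array 1 the bounds of Jchain and Ceacam1 were 0.28 and 0.0808. Kdm5d and Uty are Y-linked. The planned fits of all 12 arrays with that block, and of the 6 native arrays without it, called no gene in native cells. In the main fit of all arrays, without a block, there were 131 genes at an unadjusted p under 0.05, where 997 would be expected by chance, and Retnlg had the smallest adjusted p, 0.102. Taken without pairs, all 3 KO arrays lay on 1 side of all 3 WT arrays for 7.04% of genes, where chance gives 10%. The other genes with the smallest p-values among rises were Ceacam1, a cell adhesion molecule, Jchain, Wfdc17 and Spi1, the myeloid transcription factor PU.1. Of these 4 genes the WT levels lay at background, and those of Wfdc17 and Spi1 leave no bound above 0. Among falls they were Ankrd55 at -0.45 ± 0.14 (SE, n = 3 per group), Tgfbr3, a TGF-beta co-receptor, at -0.41 ± 0.15, Pyy, whose KO level lay at background, and Mospd4 and Acad12, at background in both groups. None of the 10 passed in that fit. Without KO array 2, 10 genes were called, all higher in KO cells, among them Retnlg, Wfdc17, Spi1, S100a8 and Lyz2. Without WT array 1 the count was 1, Retnlg, and without KO array 3 it was 1, Jchain. Xist, the RNA that silences an X chromosome in females, lay at 5.26 on native KO array 1 and 4.99 on activated KO array 1, and between 9.34 and 11.47 on the other 10 arrays. Its native difference was -2.33 ± 1.39, and the Y-linked genes Kdm5d, Eif2s3y and Uty differed by 0.77 ± 0.38, 0.75 ± 0.29 and 0.69 ± 0.33. Without KO array 1 the differences of Xist and Kdm5d were -0.71 and 0.50. The genotypes thus differed in transcripts that mark sex, and no KO against WT value was adjusted for that difference.

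The next comparison asked the same of cells cultured for 96 h with allogenic antigen-presenting cells and anti-CD3. Activated KO cells lay below activated WT cells in all 18 genes of naive and central memory T cells, with a median of -0.38 (camera, adjusted p = 1.53e-08; adjusted p = 0.586 with an estimated correlation). Igfbp4 differed by -0.89 ± 0.32 (SE, n = 3 per group) and Dapl1 by -0.71 ± 0.31. All 18 members of the glycolysis list were lower as well, median -0.25 (adjusted p = 1.56e-06; adjusted p = 0.591 with an estimated correlation); 17 of them are glycolysis genes and 1 is Pigq, a gene of GPI anchor synthesis matched through an older symbol, without which the median was -0.26 (adjusted p = 2.44e-06; adjusted p = 0.591 with an estimated correlation). Members included Aldoc, an aldolase, at -1.02 ± 0.66 and the glucose transporter Slc2a3 at -0.77 ± 0.51. Regulatory T cell genes were lower in 18 of 22 cases, median -0.17 (adjusted p = 0.000657; adjusted p = 0.586 with an estimated correlation), with Ctla4, an inhibitory receptor, at -1.37 ± 0.83, Tnfrsf4, the costimulatory receptor OX40, at -1.14 ± 0.44 and Il10 at -0.62 ± 0.62. NK-type receptors were higher in 14 of 16 cases, median 0.25 (adjusted p = 5.92e-05; adjusted p = 0.586 with an estimated correlation). Cytotoxic effectors were higher in 16 of 19 cases, median 0.18 (adjusted p = 0.000401; adjusted p = 0.586 with an estimated correlation), with the granzymes Gzme at 1.17 ± 0.67 and Gzmd at 1.16 ± 0.79. In these 5 lists 0 members passed over all genes or adjusted over the list alone. Each call rested on single arrays. Without activated KO array 3 the naive and central memory list was at adjusted p = 0.80, the regulatory list at 0.80 and glycolysis at 0.445 with the opposite direction. Aldoc and Slc2a3 then changed sign, at 0.0726 and 0.0312, and the differences of Ctla4, Il10, Tnfrsf4 and Igfbp4 were -0.0775, -0.12, -0.71 and -0.55, those of Gzmd and Gzme 0.76 and 0.74. Without activated WT array 2 the naive list was at 0.183, NK-type receptors at 0.0507 and cytotoxic effectors at 0.709, and Gzmd, Gzme and Dapl1 differed by 0.13, 0.43 and -0.42. Without activated KO array 1 both NK-type receptors and cytotoxic effectors were at 0.0992, and without activated WT array 3 the regulatory list was at 0.374, Tnfrsf4 at -0.69 and Il10 at -0.0333. Il10 lay at -0.35 without activated WT array 1. The medians shrank too: without KO array 3 to -0.0633 for the naive and -0.0191 for the regulatory list, with 0.0299 for glycolysis, without WT array 2 to -0.14 for the naive, 0.0234 for the cytotoxic and 0.14 for the NK-type list, and without KO array 1 to 0.12 for the NK-type list.

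The other 7 of the 12 lists called in activated cells also lost the call without at least 1 array. Interferon-stimulated genes had a median of 0.12 (adjusted p = 0.00528; adjusted p = 0.761 with an estimated correlation), with Ifit1, an antiviral protein, at 0.65 ± 0.51 (SE, n = 3 per group); the list was at 0.106 with the opposite direction without KO array 1, at 0.642 without WT array 2 and at 0.316 without WT array 3. Ifit1 itself differed by 0.0468 without KO array 1 and by 0.40 without WT array 3. TCR signalling genes had a median of -0.11 (0.00304; 0.761 estimated) and were at 0.605 without WT array 2 and higher, at 0.00287, without KO array 3. Cholesterol synthesis genes (-0.17, 0.00947; 0.761 estimated) were at 0.382 without WT array 1, and with the opposite direction at 0.429 without KO array 3 and at 0.878 without WT array 3. NK cell markers (0.16, 0.0247; 0.698 estimated) were at 0.352 without KO array 1, 0.406 without KO array 3 and 0.891 without WT array 2. The 71 genes with an Rpl or Rps symbol (-0.07, 0.000401; 0.755 estimated) were at 0.579 without KO array 3 and 0.40 without WT array 3, and the 61 without the kinases and the 4 others at 0.00022 (0.738 estimated). Genes with the symbol of a small RNA, of which 2 are long noncoding transcripts (-0.05, 0.00304; 0.761 estimated), were at 0.53 without KO array 1, 0.432 without KO array 2 and 0.423 without WT array 2. Chemokines and their receptors had a mean of 0.18 and a median of 0.01 that changes sign with the scaling (0.00648; 0.586 estimated), and were at 0.0992 without KO array 1, 0.483 without KO array 3 and 0.316 without WT array 3. Among its members 1, the chemokine receptor Ccr2, rose adjusted over the list alone, by 0.96 ± 0.20, and another, the chemokine Xcl1, differed by 1.08 ± 0.42, or 0.56 without KO array 3. Without KO array 1 the medians were -0.17 for interferon-stimulated and -0.0176 for small RNA genes. Without KO array 3 they were 0.12 for TCR, 0.0362 for cholesterol and -0.0285 for Rpl and Rps genes, and without KO array 2 -0.027 for small RNA genes. Leaving out WT array 2 gave 0.0354 for NK cell markers, and WT array 3 gave -0.031 for cholesterol, -0.0162 for Rpl and Rps and -0.0293 for small RNA genes. Neutrophil markers had a median of -0.03 in activated cells (adjusted p = 0.783), and their list mean lay between 5.62 and 5.82 on all 6 activated arrays.

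Across single genes, limma called 0 of 19938 between activated KO and WT cells, with 87 at an unadjusted p under 0.05. KO and WT arrays did not overlap for 1.75% of genes, against 10% by chance. Besides Ccr2, the smallest p-values among rises belonged to Rsu1 at 0.34, Dglucy at 0.56, and Dcpp2 and Clmn, both at background in each group. Among falls they belonged to Tspan32, a tetraspanin of blood cells, at -0.99 ± 0.26 (SE, n = 3 per group), Tlr1, a Toll-like receptor, at -0.55 ± 0.16, Snord73b at -0.80 (-0.50 without KO array 3), and Mir363 and Rab39b, both at background in each group. Gut homing receptors were not called (median -0.05, adjusted p = 0.459).

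Taking both states together, NK-type receptors were the list that kept its call with an estimated correlation. All 16 lay higher in KO cells, with a median of 0.37 (camera, adjusted p = 4.48e-21; adjusted p = 0.026 with an estimated correlation), and 1 of them rose adjusted over the list alone, Klre1, at 0.43 ± 0.10 (SE, n = 6 per genotype). No single array left out ended that call, whereas fry, which does not compare a list with other genes, gave an adjusted p of 0.439. The labels do not say whether native and activated arrays of a genotype share mice, and the fit took all 6 as independent. Xist was low on KO array 1 of both states, at 5.26 in native and 4.99 in activated cells. Another 16 lists were called, of which 10 were higher, and none of them held with an estimated correlation. They included neutrophil markers (median 0.58, adjusted p = 8.86e-16; adjusted p = 0.124 with an estimated correlation) and cytotoxic effectors (0.19, 3.15e-08; 0.124 estimated), whose calls outlasted every single array left out at smaller medians (0.33 for the former without native KO array 1, 0.0569 for the latter without activated WT array 2, 0.0826 without native KO array 1 and 0.12 without activated KO array 1), as did those of effector and memory, macrophage and dendritic, NK cell and chemokine genes. The other 10 each lost the call without at least 1 array, naive and central memory genes (-0.22, 2.12e-05; 0.452 estimated) without activated WT array 2 (0.215, median -0.0764) or activated KO array 3 (0.824, median -0.0145). Limma called 0 single genes, with 118 at an unadjusted p under 0.05; without native KO array 2, 3 were called, Alox5ap, Ly86 and an immunoglobulin kappa variable segment, each chosen after its values were seen. The smallest p-values among rises were those of Ccr2 at 0.61 ± 0.14, Klre1, Retnlg, Ceacam1 and Jchain. The last 3 lay at background in activated cells of both genotypes, so that their mean of both states rests on the native difference, and it is not given as a size. Falls included Ifi27l2a, an interferon-induced gene, at -0.90 ± 0.30 (-0.57 without activated KO array 3), Cpm, a carboxypeptidase, at -0.56 and Usp6nl at -0.33. Among the 4 measured sex-linked genes 3 rose and 1 fell adjusted over the list alone: Xist at -2.61 ± 0.98, Eif2s3y at 0.66 ± 0.21, Uty at 0.66 ± 0.24 and Kdm5d at 0.65 ± 0.27. On the arrays numbered 3 of the activated state the 3 Y-linked genes lay lower in KO than in WT cells.

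Whether the genotype difference itself depended on the state was tested as the interaction. Limma called 0 genes, with 86 at an unadjusted p under 0.05. The largest list shift was that of neutrophil markers, whose KO minus WT difference was lower after activation in all 12 genes (median -1.12, camera, adjusted p = 9.97e-18; adjusted p = 0.192 with an estimated correlation), and Retnlg passed adjusted over the list alone. Of the 12 genes 11, Retnlg among them, lay at background in activated cells of both genotypes, so that the shift restates the native difference with its sign turned. MHC class II genes followed, with a median of -0.75 (adjusted p = 3.92e-06; adjusted p = 0.187 with an estimated correlation) and H2-Ab1 at -2.07 ± 1.20 (SE, n = 3 per group), and 3 of the 8 lay at background in activated cells of both genotypes. Without activated KO array 3 these were -0.49 and -0.89, and the neutrophil median was -0.72 without native KO array 1 and -0.70 without native KO array 3. In all, camera called 17 lists, 16 lower and 1 higher, and 0 with an estimated correlation; fry also called 0. The single-gene differences in native and in activated cells correlated weakly, with Pearson's r of 0.0967 and Spearman's rho of 0.0404 across 19938 genes. Their standard deviation over genes was 0.121 in native and 0.148 in activated cells, each under the median standard error of 0.154. Most of these differences are thus within their error, and a low correlation cannot tell whether effects of genotype are shared between the states. Of 100 relabellings of the arrays within the states, the real one included, 57 gave a correlation at least as far from 0, on either side of it, and the largest size was 0.444. That count mixes relabellings of different kinds if the numbers pair the native arrays. Among the 45 that part all 3 native pairs, as the real one does, 11 were as far from 0, and those other than the real one lay between -0.135 and 0.115. The other 55 part 1 pair, and 46 of them were as far from 0. Leaving out native WT array 1 moved r to 0.00376, native KO array 2 to 0.0332, activated KO array 1 to 0.0370, activated WT array 2 to 0.0560 and native WT array 3 to 0.147.

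The last 2 comparisons asked what culture with antigen-presenting cells and anti-CD3 did to cells of each genotype. No group was cultured without this stimulation. Changes on activation can thus not be told apart from those of culture itself or of fresh isolation. Il2ra, the high-affinity IL-2 receptor chain, rose by 6.01 in WT and 5.55 in KO cells (64.4-fold and 47.0-fold, SE of the log2 value 0.20, n = 3 per group). The costimulatory receptor Tnfrsf9 rose by 4.02 and 3.99 (SE 0.29), and Lrrc32, which holds latent TGF-beta at the cell surface and lay at background in native cells, by at least 4.64 and 4.38. No call of a gene list on activation held with an estimated correlation, in either genotype, while fry called 16 lists in WT and 18 in KO cells. Among 22 regulatory T cell genes 14 rose and 4 fell in WT cells (camera, adjusted p = 3.51e-06; adjusted p = 0.28 with an estimated correlation) and 10 rose and 4 fell in KO cells (0.000729; 0.336 estimated). Adjusted over the list alone, 15 and 4 passed in WT and 11 and 4 in KO cells. Itgae, the CD103 integrin chain, was among those that fell, at -3.88 in WT cells (SE 0.40). Foxp3, the lineage factor of CD4 regulatory T cells, fell by 0.34 in each genotype (SE 0.11, adjusted p = 0.0447 and 0.0444), to a level at background that leaves its size without a bound above 0. That call was lost in WT cells without any 1 of the 6 WT arrays, at adjusted p from 0.0563 to 0.18. In KO cells it was lost without each KO array except activated array 3, at 0.0964 to 0.156, and with the replicate number as a block it was lost in both (0.051). Cytotoxic effectors split. In WT cells 9 of 19 rose and 3 fell, in KO cells 9 rose and 4 fell (adjusted p = 0.00794 and 0.00627; adjusted p = 0.489 and 0.441 with an estimated correlation). Adjusted over the list alone 11 rose and 4 fell in WT, 11 rose and 6 fell in KO cells. Gzmb rose by 5.15 in WT and 4.82 in KO cells (SE 0.26). Gzmc and Gzmd, at background in native cells, rose by at least 4.78 and 2.25 in WT and 5.35 and 3.38 in KO cells, and Gzmd in WT cells by at least 1.17 without activated WT array 3. All are granzymes.

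Cell cycle, glycolysis and cholesterol synthesis genes were called higher in both genotypes. Of 31 cell cycle genes 30 rose and 0 fell in each genotype, with medians of 2.42 in WT and 2.31 in KO cells (camera, adjusted p = 3.22e-40 and 6.2e-38; adjusted p = 0.158 and 0.185 with an estimated correlation). Adjusted over the list alone 30 and 31 rose. Bub1, a mitotic checkpoint kinase, rose by 4.23 and 4.13 (SE 0.13, n = 3 per group) and Aurkb, a mitotic kinase, by 4.22 and 3.73 (SE 0.21). Of the 17 glycolysis genes of that list 14 rose in WT and 13 in KO cells, and 0 fell, with medians of 1.87 and 1.74 (adjusted p = 9.36e-14 and 9e-11; adjusted p = 0.245 and 0.283 with an estimated correlation); with Pigq, which did not pass, the medians of 18 members were 1.82 and 1.57 (adjusted p = 5.7e-13 and 7.25e-10; adjusted p = 0.28 and 0.311 with an estimated correlation). Adjusted over the list alone, with or without Pigq, 15 rose in WT cells, and 14 rose and 1 fell in KO cells. The lactate exporter Slc16a3 rose by 3.81 and 3.31 (SE 0.31) and Aldoc, at background in native cells, by at least 4.80 and 3.74. Of 14 cholesterol synthesis genes 13 rose in each genotype, with medians of 2.14 and 1.89 (adjusted p = 3.08e-15 and 7.58e-14; adjusted p = 0.28 and 0.299 with an estimated correlation), or 14 and 13 adjusted over the list alone. Sqle, squalene epoxidase, rose by 3.04 and 2.83 (SE 0.22). Of 20 genes of the ATF4 and unfolded protein responses 10 rose and 2 fell in each genotype (adjusted p = 0.000298 and 0.000357; adjusted p = 0.56 and 0.497 with an estimated correlation), 13 and 2 in each adjusted over the list alone. Asns, asparagine synthetase, rose by 4.51 and 3.97 (SE 0.34), and Dnajb9, an endoplasmic reticulum chaperone, fell, at -3.51 and -3.59 (SE 0.29). Scd1, a fatty acid desaturase at background in native cells, rose by at least 5.36 in WT and 3.74 in KO cells. The KO bound was lowered by activated KO array 3, at 6.76, under that array's background level, where the other activated arrays lay between 11.29 and 11.93; without it the bound was 5.37. Bnip3 rose by 5.09 and 4.44 and Ak4, at background in native cells, by at least 4.47 and 3.52, both known targets of the hypoxia response. Without activated KO array 3 the KO bounds of Aldoc and Ak4 were 4.84 and 4.67.

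**Figure D3:**
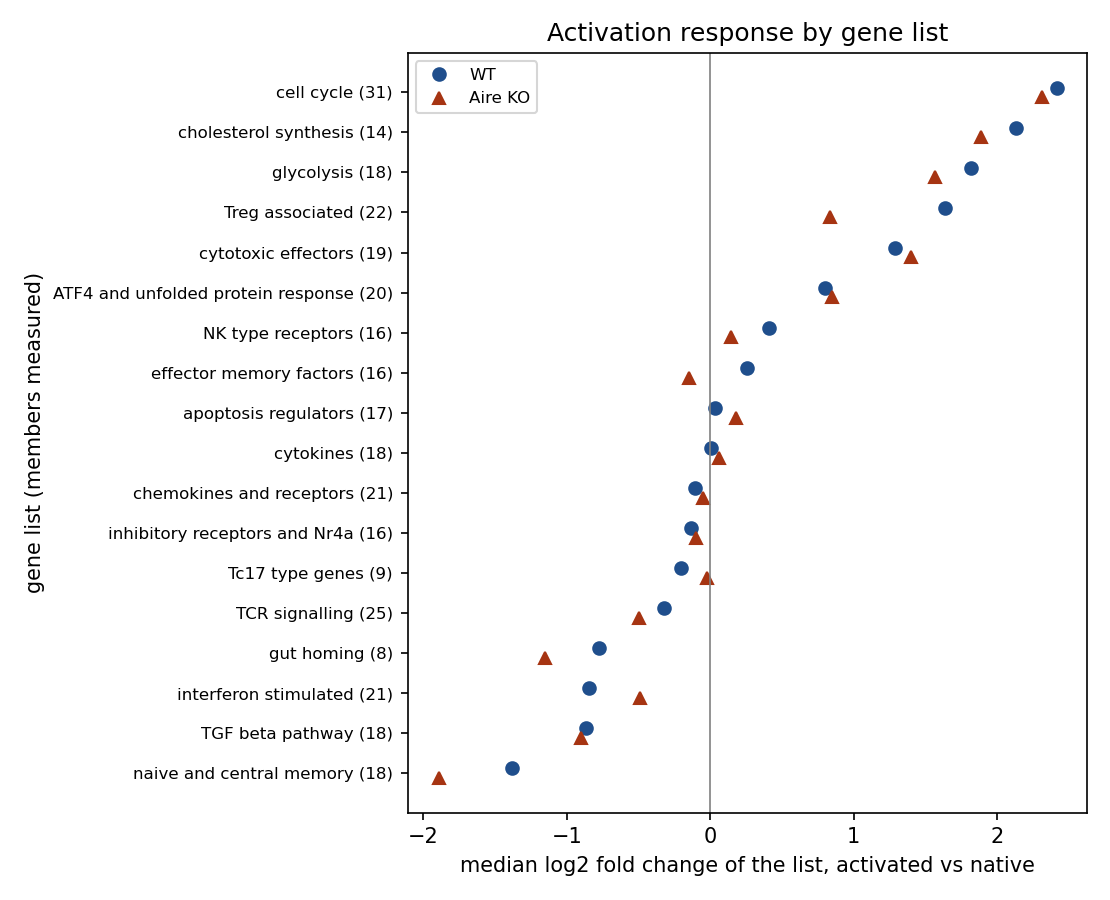
Median log2 change on activation (x axis) of the T cell, metabolic and stress gene lists (y axis, members measured in brackets), with circles for WT and triangles for KO cells. Among the plotted lists, which leave out immediate early genes, cell cycle genes lie highest, at 2.42 and 2.31, and naive and central memory genes lowest, at -1.38 and -1.89.

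Naive and central memory genes were called lower on activation in both genotypes. Of 18 naive and central memory genes 12 fell and 1 rose in WT cells, and 14 fell and 1 rose in KO cells, with medians of -1.38 and -1.89 (camera, adjusted p = 1.1e-06 and 6.95e-10; adjusted p = 0.479 and 0.311 with an estimated correlation), and 15 fell in each adjusted over the list alone. Klf2, a transcription factor of T cell quiescence, fell, at -3.55 and -4.07 (SE 0.36, n = 3 per group), and S1pr1, the receptor for exit from lymphoid tissue, at -3.25 and -3.99 (SE 0.82). Of 19 immediate early genes 11 fell in WT and 14 in KO cells, and 1 rose in each (adjusted p = 1.28e-07 and 8.67e-10; adjusted p = 0.408 and 0.311 with an estimated correlation); 16 fell in each adjusted over the list alone. Fosb, a subunit of the AP-1 transcription factor, fell, at -3.96 and -4.44 (SE 0.50). Of 18 TGF-beta pathway genes 11 fell and 2 rose in each genotype (adjusted p = 0.000472 and 0.000272; adjusted p = 0.28 and 0.299 with an estimated correlation), 11 and 12 falling adjusted over the list alone. Smad7, an inhibitor of that pathway, fell, at -2.97 and -3.02 (SE 0.33). Among 8 gut homing receptors 3 fell and 2 rose in WT cells and 4 fell and 1 rose in KO cells (adjusted p = 0.0348 and 0.0169; adjusted p = 0.28 and 0.299 with an estimated correlation); 5 and 4 fell adjusted over the list alone. The KO call was lost without activated KO array 3 (0.0687). Itga4, an integrin chain for gut homing, fell, at -3.61 and -3.87 (SE 0.27). Ccr9, the receptor for a chemokine of the small intestine, fell to background, so that -4.76 and -4.11 are the smallest falls the levels allow.

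Other T cell groups changed in part. NK-type receptors were called higher in WT cells, with 6 of 16 rising and 2 falling (adjusted p = 0.0211; adjusted p = 0.549 with an estimated correlation), a call lost without activated WT array 1 (0.067). In KO cells 6 rose and 3 fell and the list was not called (adjusted p = 0.154), but was without native KO array 1 (0.0395) or activated KO array 3 (0.0477). Adjusted over the list alone 6 rose and 3 fell in WT, 6 rose and 4 fell in KO cells. The difference between the genotypes, the interaction, had a median of -0.22 (adjusted p = 0.0015; 0.393 with an estimated correlation). That call was lost without native KO array 1 (0.308, median -0.0863) or activated KO array 3 (0.152, median -0.0906), and the median was -0.0574 without activated WT array 1 and -0.13 without native WT array 3. Klrk1, the activating receptor NKG2D, rose by 3.07 in WT and 2.37 in KO cells (SE 0.18, n = 3 per group), and Klrg1 fell to background, so that -0.54 and -0.53 are the smallest falls the levels allow, or -0.20 in WT cells without native WT array 2, and in KO cells -0.28 without native KO array 1 and -0.32 without activated KO array 2. Inhibitory receptors went both ways and were not called (adjusted p = 0.704 in WT and 0.89 in KO cells), with a median below and a mean above 0 in each genotype. Entpd1, the ectonucleotidase CD39, rose by 3.41 and 3.20 (SE 0.29), while Nr4a1, an early T cell receptor target, fell, at -2.87 and -3.06 (SE 0.54). Interferon-stimulated genes fell in 8 of 21 cases in WT and 3 in KO cells, or 11 and 3 adjusted over the list alone (adjusted p = 0.00542 and 0.0252; adjusted p = 0.683 and 0.658 with an estimated correlation). In KO cells that call was lost without native KO array 1 (0.16), activated KO array 2 (0.122) or activated KO array 3 (0.569). TCR signalling genes fell in 4 of 25 cases in WT and 8 in KO cells, or 4 and 10 adjusted over the list alone (adjusted p = 0.0143 and 0.000414; adjusted p = 0.743 and 0.563 with an estimated correlation), and the calls were lost without activated WT array 3 (0.0691) and activated KO array 3 (0.125). Cytokines (6 of 18 rose in WT, 4 rose and 1 fell in KO cells) and chemokines and their receptors (3 of 21 rose in each, 4 fell in WT and 5 in KO cells) were not called, with the same counts adjusted over the list alone. Ccr2 rose by 2.56 and 3.27 (SE 0.20) and Ccl5, a chemokine of effector T cells, fell, at -2.02 and -2.24 (SE 0.20).

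Of the lists of other cell types, erythroid and platelet markers were called lower in both genotypes. Of 8 members 5 fell and 0 rose in each, or 5 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.0131 and 0.00217; adjusted p = 0.28 and 0.299 with an estimated correlation), among them Car1, an erythroid carbonic anhydrase, which fell to background with -3.39 and -3.83 as the smallest falls the levels allow (n = 3 per group). Neutrophil markers fell in 5 of 12 cases in KO cells, where 1 rose, and the list was called lower (0.000357; adjusted p = 0.453 with an estimated correlation); 11 fell adjusted over the list alone. In WT cells 0 fell and 1 rose (adjusted p = 0.656). The difference between the genotypes is the interaction given for that list. MHC class II genes were called lower in KO cells (4 of 8 fell, 5 adjusted over the list alone, adjusted p = 0.0209; adjusted p = 0.336 with an estimated correlation), a call lost without activated KO array 3 (0.125), and were not called in WT cells (0.567). B cell markers were called lower in KO cells (4 of 15 fell, as adjusted over the list alone, adjusted p = 0.0169; adjusted p = 0.441 with an estimated correlation), a call lost without activated KO array 1 (0.0555), and not in WT cells (0.17). Plasma cell (0.303 in WT and 0.647 in KO cells), macrophage and dendritic (0.808 and 0.186) and NK cell markers (0.865 and 0.647) were not called in either, though macrophage and dendritic markers were called lower in KO cells without native KO array 2 (0.022), with medians in KO cells of 0.14 for plasma cell and 0.12 for NK cell markers.

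Activation called 4107 genes in WT cells (limma, 1937 higher and 2170 lower) and 4002 in KO cells (1739 higher and 2263 lower), of 19938 tested. Leaving out activated KO array 3 turned the KO split to 2668 higher and 2223 lower. The WT split turned to 1526 and 1439 without native WT array 1 and to 2339 and 1752 without activated WT array 2. After a second quantile normalization the split was 2909 higher and 2052 lower in WT, and 2643 and 2137 in KO cells. Of the called genes 942 rose and 715 fell at least 2-fold in WT cells, and 818 rose and 806 fell in KO cells. Both genotypes shared 3405 calls, all in the same direction, where independent calls would share 169 higher and 246 lower genes; 1548 rose and 1857 fell. Of the genes called in WT cells 4103 (99.9%) had the same sign in KO cells. Log2 changes correlated between the genotypes at Pearson's r of 0.959 and Spearman's rho of 0.874 across 19938 genes, with no array in common.

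**Figure D4:**
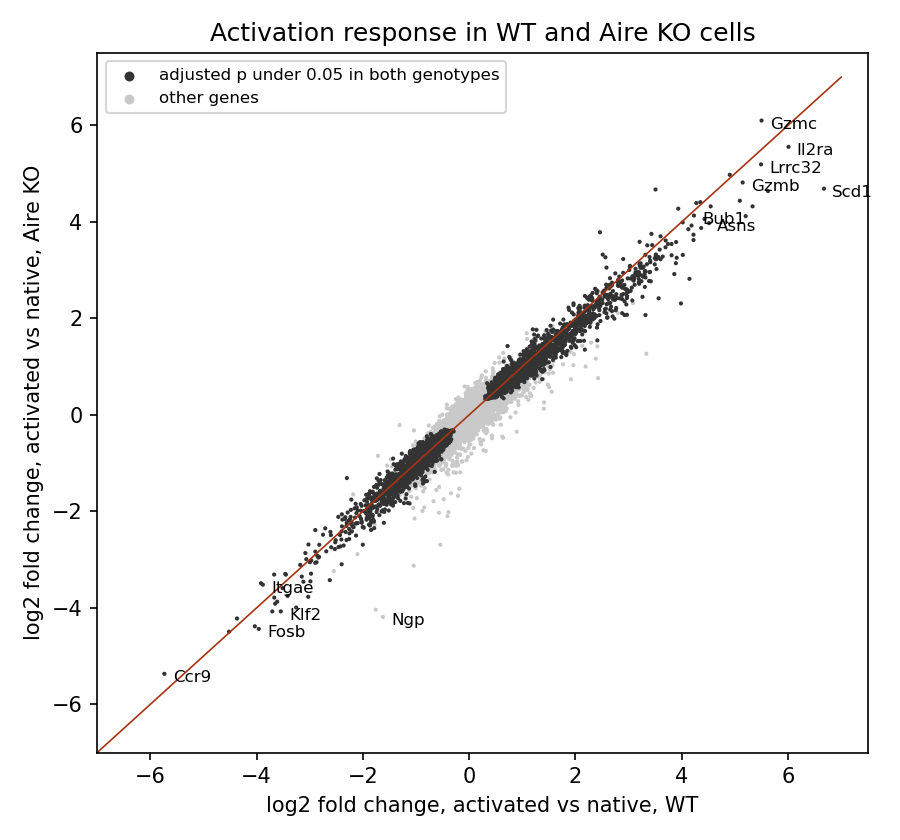
Log2 change on activation in WT cells (x axis) against that in KO cells (y axis), with 1 point per gene for 19938 genes, black where called in both genotypes, and a line of equality. The values follow the line with Pearson's r of 0.959, and Il2ra lies at 6.01 and 5.55.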

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

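The splits of the arrays and the test of each list's interaction were planned, while the 6 tests that weigh the 3 patterns of neutrophil transcripts, NK-type receptors and activated KO array 3 were chosen after the results had been seen.

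The difference between KO and WT cells changed from native to activated cells for 17 gene lists, by a test of that difference itself (camera on the interaction, adjusted p from 9.97e-18 to 0.0257). With an estimated correlation the adjusted p ran from 0.187 to 0.78, and 0 lists were called, as with fry. The median interaction (log2) was -1.12 for neutrophil markers, of which 11 of 12 lay at background in activated cells of both genotypes, so that the value restates their native difference with its sign turned. It was -0.75 for MHC class II genes, -0.38 for naive and central memory genes, -0.34 for the glycolysis list, -0.24 for NK cell markers, -0.23 for regulatory T cell genes, -0.22 for NK-type receptors and -0.22 for cell cycle genes. Smaller shifts were -0.20 for both immediate early genes and inhibitory receptors, -0.14 for effector and memory genes, -0.11 for both macrophage and dendritic markers and genes with an Rpl or Rps symbol, -0.10 for plasma cell markers, -0.0762 for TCR signalling genes and -0.0745 for B cell markers. Interferon-stimulated genes moved the other way, at 0.35.

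The neutrophil, MHC class II, cell cycle, and Rpl and Rps calls outlasted every single array left out, and the other 13 did not. All 17 medians shrank by over 1.5 times or changed sign without at least 1 array. Among the 4 the median was -0.72 for neutrophil markers without native KO array 1 and -0.70 without native KO array 3, -0.49 for MHC class II genes without activated KO array 3, and for cell cycle genes -0.11 without that array, -0.0944 without activated WT array 1 and -0.12 without native KO array 3. For Rpl and Rps genes it was -0.0547 without activated KO array 3, -0.071 without activated WT array 3 and -0.0683 without native WT array 2. Without activated KO array 3, adjusted p was 0.122 for regulatory T cell genes and inhibitory receptors, 0.855 for naive and immediate early genes, 0.351 for effector and memory genes, 0.152 for NK-type receptors and 0.794 for glycolysis, and TCR genes turned direction (0.0124). Without activated WT array 2 it was 0.227 for naive genes, 0.482 for TCR, 0.469 for interferon, 0.707 for B cell and 0.211 for macrophage and dendritic genes. Without native KO array 1 it was 0.308 for NK-type receptors, 0.656 for NK cell markers and 0.292 for B cell markers, and without activated KO array 1 interferon genes turned direction (0.292) and plasma cell markers were at 0.137. Some of these lists also lost the call without other arrays, at adjusted p from 0.0549 to 0.994.

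Among the transcript clusters without a single gene symbol, which the comparisons of named genes left out, 2 were called in native cells in a fit of the whole table (limma, n = 3 per group). The first, annotated with 4 symbols, was higher in KO cells by at least 2.45, since its WT levels lay at background (fitted difference 3.59, adjusted p = 0.00388), at 9.36, 8.83 and 7.92 on KO arrays 1, 2 and 3, at 5.42, 4.98 and 4.96 on WT arrays, and between 4.85 and 5.22 on the activated arrays. The second, with no symbol, was higher by at least 0.69, again from WT levels at background (fitted difference 1.62, adjusted p = 0.0246), at 6.75, 7.33 and 6.74 against 5.19, 5.50 and 5.25.

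All 12 neutrophil markers lay higher in native KO cells, with a median of 1.12, and a raised floor of the native KO arrays was argued against by 1027 olfactory receptor genes, whose median difference was 0.0334. Of these genes 642 lay higher, and camera called them higher as a list (adjusted p = 1.74e-05, and 0.857 with an estimated correlation). That shift is small beside 1.12 but of the size of the smallest medians among the called lists. Granulocyte-lineage cells carried over with the isolated cells are a candidate source. The test of this decided nothing: 91.7% of the markers (11 of 12) lay at least 0.5 higher, which restates the rise that prompted it. With members at background at their bound, 8 of the 12 lay above 0. Ngp, an abundant marker, lay at 11.09, 7.26 and 10.34 on KO arrays 1, 2 and 3 and at 8.77, 7.03 and 5.43 on WT arrays. S100a8 (8.96, 5.89 and 8.25 against 6.87, 5.89 and 5.47) and Lyz2 (9.62, 6.51 and 9.02 against 7.03, 6.32 and 5.24) moved with it. Isolation of CD8+CD28low cells is meant to leave such cells out, but how it was done is not given, so how far it did so is not known. Of the 12 markers 1, Mmp9, rose on activation in the studied WT cells, by at least 2.97 from a level at background. KO array 2 lay within the range of the WT arrays in these 3 genes but not in Retnlg, at 7.74 against 5.48 to 6.56, so the excess is not uniform in the group. Whether more such cells came with the genotype or with single isolations stays open and was not tested.

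NK-type receptors were higher in native KO cells, and neither explanation tested was excluded. NK cells carried over could bring them, and the test of this decided nothing: 6 genes chosen as typical of NK cells had a median difference of 0.32 against 0.39 for 9 receptors that memory CD8 T cells also carry, but the 6 include the adaptor Sh2d1b1 and Itga2, which rose by 1.32 on activation in the studied WT cells (adjusted p = 0.0128; lost at 0.0529 without activated WT array 1 and at 0.0554 without native WT array 3). The same carried-over cells as for the neutrophil transcripts could bring them too, but the test of this cannot decide it. Its covariate, the neutrophil list mean, itself differed between native KO and WT cells. A list that differs by genotype can shrink with that covariate whatever the cause. With it the median went from 0.47 to 0.29, at adjusted p = 0.000103 (camera) with the preset and 0.314 with an estimated correlation (1.43e-28 to 0.435 over all alternatives). The requirement that the call hold with both correlations was set after the first of these values had been seen. As with granulocytes, isolation of CD8+CD28low cells is meant to leave NK cells out, but how far it did so is not known. A larger share of memory-type cells among KO cells, the biological alternative, stays open and was not tested directly.

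Activated KO array 3 stood apart from the other 2 arrays of its group. The level of a gene explained 48.9% of the variance of the array's deviations. With that trend removed the glycolysis list still lay at -0.45 (-0.49 without Pigq), below the central range of 10000 random lists matched on level (-0.24 to 0.19). That list was chosen after its low level there had been seen, and the random lists hold unrelated genes. Their range is too narrow for genes that move together, so whether a compressed range is the whole cause stays open. Naive and central memory genes, which fall on activation, lay at -1.14 against the other 2 arrays (-0.76 with the trend removed, where random lists reached from -0.28 to 0.22). These genes thus showed no smaller activation response, but they too were chosen after their values were seen. Cell cycle genes, examined first, decide nothing, at -0.22 before and 0.26 after the trend was removed. Hypoxia response genes were lowest among the lists examined (-1.13), and Egln3, a hypoxia target chosen after its values were seen, was at 7.15 against 10.9 to 11.7 on the other activated arrays. Whether the culture of that replicate differed was not tested, and the design gives no biological group by which to test it.

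With 3 arrays against 3 there are 10 splits, and the share of splits with as many calls cannot be under 0.1. A real count of 0 is met by every split, so for the comparisons of genotypes and the interaction the splits decide nothing. In native cells the real split called 0 genes and the highest other 3, and 10 of 10 splits called as many. With the native arrays taken as paired by number, the highest count among splits that part all 3 pairs, as the real one does, was 0. The highest count of all came from a split that parts 1 pair. In activated cells the real split called 0, and the highest other 15, with all 10 splits as large; that split sets KO array 1, WT array 1 and WT array 3 against the rest. On activation the real split called 4107 genes in WT and 4002 in KO cells, 1 of 10 splits was as large in each, and the highest other called 0. For the mean of both states and for the interaction 100 of 100 splits within the states called as many as the real 0, with 0 as the highest other.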

How the results depend on the processing

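The covariate, the fits without 2 arrays, the native arrays alone with the experiment as a block, the gene-by-gene array weights and the lists without misplaced members were chosen after the data had been seen; the other alternatives were planned. Signal over background limits a difference to a bound for a gene at background in 1 of the groups compared, and leaves no size for a gene at background in both, as Aire is in each comparison. Where a cause is not named below, the cause was not tested.

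In native cells the count of genes that differed between KO and WT went from 0 to 1 without the dimmest 40% of genes, where fewer genes are adjusted for, 2 over the whole table, 1 with trended and robust eBayes, 3 with array weights, 2 with gene-by-gene weights, 43 at unadjusted p under 0.05 and at least 1.5-fold, and 14 in the 6 native arrays alone with the experiment number as a block. The default array weights stopped without converging and gave activated KO array 1 a weight of 4.87e-06, so the gene-by-gene weights were added after those calls had been seen. At unadjusted p under 0.05 and at least 1.5-fold, the count was 14 in activated cells, 15 for the mean of both states and 33 for the interaction, which are looser thresholds by construction. On activation, WT cells had 7687 calls over the whole table, which holds more transcript clusters, 7609 with array weights, 6928 with gene-by-gene weights, 1657 at 2-fold or more and 6505 without the 2 arrays of narrowest range. KO cells had 7526 over the whole table, 6932 with gene-by-gene weights, 1624 at 2-fold or more and 2190 without the 2 arrays with Xist at the floor.

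Camera with an estimated correlation called 2 lists in native cells, 0 in activated cells, 1 for the mean, 0 for the interaction and 0 on activation in WT and 0 in KO cells. Fry called 0 lists in native cells, 0 in activated cells, 0 for the mean and 0 for the interaction. Without the dimmest 40% of genes, 11 lists were called for the interaction. The correlation of the genotype differences between states was 0.0454 without the 2 arrays of narrowest range.

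Leaving out each array in turn, the gene count ran from 0 to 10 in native cells, 0 to 0 in activated cells, 0 to 3 for the mean, 0 to 0 for the interaction, 2805 to 4091 for WT activation and 2823 to 4891 for KO activation. The highest native count came without native KO array 2. List counts ran from 12 to 19 in native cells, 6 to 13 in activated cells (6 without KO array 3), 11 to 20 for the mean (11 without native WT array 3), 12 to 19 for the interaction, 14 to 15 in WT and 14 to 19 in KO activation. The correlation of genotype differences ran from 0.00376 to 0.147 and that of activation differences from 0.910 to 0.959. Among genes named, Aire on activation in KO cells ran from -0.0184 to 0.12, reversing without activated KO array 3, and for the mean of both states it lay on both sides of 0, from -0.0412 to 0.0332. In activated KO against WT cells Aldoc ran from -1.69 to 0.0726 and Slc2a3 from -1.30 to 0.0312, both reversing without activated KO array 3.

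With the replicate number as a block 0 genes were called in each genotype comparison and in the interaction, 4498 on WT activation and 4414 on KO activation. Apart from the neighbours of Aire, CD4 markers and Foxp3, the block ended the call of cholesterol synthesis (0.0583) and added interferon-stimulated (0.0165) and thymocyte genes (0.0479) for the mean, and added CD4 markers for the interaction (0.0399). It also ended the call of Acss2 in KO cells (0.0529) and added that of Ncr1 in WT cells (0.0131) on activation, and changed no other call of a list or of a gene named. Between activated WT and KO arrays, array 1 correlated best with its own number, while arrays 2 and 3 did not.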

Other observations

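The 6 lists used here were drawn up after the results on single genes had been seen, and so were the tests on them; the genes named here were chosen after their values were seen. On activation, targets of the hypoxia response rose in both genotypes: 16 of 28 in WT and 13 in KO cells, and 0 fell (camera, adjusted p = 2.2e-12 and 3.93e-08; adjusted p = 0.155 and 0.271 with an estimated correlation). Ak4, an adenylate kinase, and Plod2, a collagen-modifying enzyme, both at background in native cells, rose by at least 4.47 and 3.11 in WT and 3.52 and 2.48 in KO cells (n = 3 per group). Activated KO array 3 had a mean level of this list of 8.12, where the other activated arrays lay between 9.63 and 10.1. Fatty acid synthesis and desaturation genes rose in 11 of 15 cases in WT and 10 in KO cells, where 1 fell (adjusted p = 1.99e-08 and 1.15e-06; adjusted p = 0.129 and 0.168 with an estimated correlation). The latter was Acss2, an acetyl-CoA synthetase, whose call was lost without native KO array 1 (0.0832), 2 (0.1235) or 3 (0.1111). The desaturase Fads2 rose by 5.20 and 4.12 (SE 0.49) and Scd2 by 3.64 and 3.28 (SE 0.21). Serine and one-carbon metabolism genes rose in 8 of 10 cases in WT and 7 in KO cells, with 0 falling (adjusted p = 3.74e-08 and 4.27e-08; adjusted p = 0.129 and 0.168 with an estimated correlation). Among them Tyms, thymidylate synthase, rose by 2.42 and 2.56 (SE 0.25), Psat1 by 2.20 and 2.17 (SE 0.18) and Mthfd2 by 2.07 and 2.01 (SE 0.22).

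Genes first described on NK cells were also divided into 9 receptors that memory CD8 T cells carry too and 6 genes chosen as typical of NK cells, a set that includes the adaptor Sh2d1b1. Of the 9 receptors 6 rose and 1 fell in each genotype (camera, adjusted p = 7.71e-05 and 0.000426; adjusted p = 0.155 and 0.241 with an estimated correlation), with Klrk1 at 3.07 and 2.37 (SE 0.18, n = 3 per group). Of the 6 genes 1 rose, Itga2, by 1.32 (adjusted p = 0.0128, and 0.0529 without activated WT array 1 or 0.0554 without native WT array 3), and 1 fell in WT cells, and 0 rose and 2 fell in KO cells (adjusted p = 0.741 and 0.413). In KO cells the 2 that fell were Ncr1 and Klra8, to background, with -0.82 and -0.52 as the smallest falls the levels allow (-0.51 and -0.22 without native KO array 1); the call of Ncr1 was lost without native KO array 1 (0.0529). The difference between these lists was not tested.

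Differences between KO and WT cells may carry a difference in the sex of the mice. Xist lay at the floor on KO array 1 of both states, and Y-linked transcripts were higher in KO than in WT cells between arrays of the same number, except on activated array 3, where Kdm5d, Uty and Eif2s3y lay lower, at -0.25, -0.33 and -0.11. Y-linked transcripts were also seen on the 10 arrays with Xist, Kdm5d at 7.32 to 8.70, the lowest on activated KO array 3 at the edge of that array's background. Without those 2 arrays, an alternative chosen after the data had been seen, limma called 0 genes in native and 0 in activated cells. Camera called 19 lists in native and 8 in activated cells, against 18 and 12 with all arrays. In native cells neutrophil markers (adjusted p = 1.15e-13) and NK-type receptors (3.13e-09) were still called higher, while in activated cells NK-type receptors (0.0805) and cytotoxic effectors (0.106) were not called. That fit leaves out the arrays without Xist and does not adjust for the sex make-up of the others, so a difference in sex stays open for the differences between genotypes.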
